A study of Mus musculus with 6 samples.

How the data were processed

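Total RNA from snap-frozen kidneys was extracted with TRIzol and labelled with biotin by the GeneChip WT PLUS kit, per the labels' protocols. Each of the 6 arrays belongs to 1 female mouse kidney sample, 3 from the saline group and 3 from the metformin group, and the labels call them biological replicates. The deposited values are log2 expression per transcript cluster and array, made by the authors with RMA (background correction, quantile normalization and a summary over probes) and Transcriptome Analysis Console 4.0, per the submitters' processing notes. The variant of RMA, the probe definition and the software settings are not given in the sources used here. The values run from 1.94 to 19.9. A log2 value above 16 exceeds what a scanner of 16 bits records. A step that stretches the scale may have been applied before deposit, which was not tested, and fold changes hold on the deposited scale. The array medians range from 4.67 to 4.86, so the arrays' distributions were not identical as deposited.

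The table holds 65956 transcript clusters. The platform annotation used here lists 32750 of them, 30604 with 1 gene symbol and 2146 with several, and 33206 are not listed and stay unnamed here. Symbols were updated through the Entrez number where the RefSeq table of assembly GRCm38.p6 held it (22818 matched, 827 symbols changed). That table gave names and RNA classes only. Pkd2 has no cluster of its own under this annotation and was not analysed here. The 33.3% of clusters with the lowest mean over the 6 arrays were left out (mean at or under 4.03), which left 43971. For each gene the cluster with the highest mean over all arrays was kept, and 266 genes had several. Identical values on all arrays are shared by 271 of the genes tested, which the array cannot tell apart.

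The 22087 genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), metformin against saline, two-sided, without covariates. The Benjamini-Hochberg adjusted p had to be under 0.05. A second count took an unadjusted p under 0.05 with at least 1.5-fold. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Before the data were examined, 34 gene lists and 18 lists of cell type markers were fixed, of which 51 had at least 3 measured members. The list of Y-linked genes, a check of the samples, had 1 and was not tested (change -0.13). Of the 51 lists 26 were called, 6 up and 20 down. With an estimated correlation 0 were called by camera (3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.578). The fry test, which asks whether a list's genes move one way and does not compare them with other genes, called 5: cholesterol, NRF2, cAMP and vasopressin, xenobiotic and erythroid genes. Members of a list were also adjusted over the list alone. List scores per array are mean deviations of the members from each gene's mean over the 6 arrays. Intervals come from 2000 bootstrap draws of genes at the 95% level.

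Genes named in the text were fixed by a rule before the data were examined: Pkd1 and Pkd2; among genes past the adjusted threshold the 15 with the largest fold change in each direction, leaving out predicted genes, small RNAs and unnamed clusters; and from each list up to 4 members with the smallest p and any member past the threshold. The rule took 286 genes, and the text names a part of them for the lists. Ucp1, Xist, Malat1, Snora62 and Snora75 fall outside it and were chosen after their values were seen. Changes are metformin minus saline in log2 units unless a fold is stated, and SE is that of the limma fit.

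Deviations from the group means correlated across genes at 0.118, 0.145 and 0.541 for the replicate numbers 1, 2 and 3 of the labels. The check used here took this as a pairing of the samples. Among pairs of different numbers saline 2 with metformin 1 reached 0.299, above the same-number values of 1 and 2. Not every sample correlated best with its own number, so these values do not establish that the numbers pair the samples. Genes are not independent replicates, and what a number stands for is not given in the sources used here. The fit with the number as a block was an alternative, named beside a result only where it changed a call. Other alternatives were leaving out each replicate, median-centring, quantile normalization, other filters, the mean over a gene's clusters, all clusters, trend and robust options, array weights, a plain test per gene, 2-fold, fry and the estimated correlation. Simulated data took the real genes' means and spread but drew each gene independently. On them the test recovered 2%, 28%, 72% and 96% of 50 genes each changed by 1.25, 1.5, 2 and 4-fold. Far fewer of the 22087 genes were changed there than the 15.8% called in the real data. These shares therefore do not give the power of the real test. The false share among its calls was 4.81%, and the list test called the 1 shifted list of 51 and 0 others. Genes of the real lists are correlated (estimated at 0.786 for macrophage markers), so the simulation does not show how many real calls are false. With 3 arrays against 3 an exact permutation test of a single value cannot give a p below 0.1, so gene tests rest on limma's shared estimate of the spread.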

Results

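Whole-kidney total RNA was profiled on 6 single-colour expression arrays from female Pkd1 miR transgenic mice, a polycystic kidney disease model in which a transgene targets Pkd1. Saline was injected in 3 mice, and 3 received metformin, a biguanide drug for diabetes that inhibits mitochondrial complex I and activates AMPK, at 150 mg per kg per day into the peritoneum. Treatment ran from postnatal day 35 to day 63, when the kidneys were taken. The samples are labelled as biological replicates. The array medians lay between 4.67 and 4.86 on the log2 scale. The upper quartiles lay between 7.01 and 7.12 on the saline arrays and between 7.21 and 7.34 on the metformin arrays. Correlations across transcript clusters were 0.993 to 0.995 within saline, 0.994 to 0.996 within metformin and 0.984 to 0.993 between groups.

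The comparison asks which kidney transcripts differ after metformin in this model. In the metformin kidneys 10 of 30 proximal tubule markers fell, as did 17 of 26 genes of amino acid metabolism, 14 of 30 of fatty acid oxidation and 9 of 19 of fatty acid synthesis. Of the cell cycle list 12 of 34 genes rose, of the matrix list 6 of 34 and of the macrophage list 3 of 25, with array scores of the matrix and macrophage lists that overlapped between the groups. The camera test called these 7 lists, and called none of them with an estimated correlation (adjusted p = 0.578 to 0.743 with an estimated correlation). With the preset correlation camera called 26 of 51 lists, and 9 to 32 in other splits of the 6 arrays into 3 and 3. Of 22087 genes tested with limma, 3488 changed at an adjusted p under 0.05 (15.8%), with 1482 higher and 2006 lower. The median change among these was 1.56-fold upwards and 1.57-fold downwards. At least 2-fold changes were seen in 149 of the genes that rose and 322 of those that fell. The values of the groups did not overlap in 8229 genes (37.3%), where chance gives 10%. The first principal component held 61.4% of the variance and separated the groups. A looser description, an unadjusted p under 0.05 with at least 1.5-fold, took in 2629 genes, 1162 higher and 1467 lower, and 7080 genes had an unadjusted p under 0.05 where chance would give 1104. Among protein-coding genes, 639 rose and 1737 fell. Small structural and regulatory RNAs moved with the groups too, with a mean deviation of -0.24, -0.17 and -0.17 on saline arrays 1 to 3 and 0.23, 0.13 and 0.22 on metformin arrays 1 to 3. The split into higher and lower depended on the features and on scaling. Over all 43971 clusters past the filter, of which 21547 have no or several symbols, 5553 were higher and 2221 lower. Among genes 42.5% of those changed were higher as deposited, 25.2% after median-centring and 20.7% after quantile normalization, which moved the median change of all genes from 0.02 to -0.10. The count also rested on single arrays. It was 842 without saline replicate 1, 1247 without metformin replicate 1, 1368 without metformin replicate 2, 1956 without metformin replicate 3, 1965 without saline replicate 3 and 3961 without saline replicate 2. A plain equal-variance test per gene called 44 genes (14 higher, 30 lower), and limma with the adipocyte marker score in the fit, chosen after seeing the data, 212 (141 higher, 71 lower).

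The gene with the greatest rise among those named by the fixed rule was Ccn1 at 4.61-fold, a matricellular target of YAP, from 11.14 ± 1.11 to 13.35 ± 0.83 log2 units (SD, n = 3 per group). Mgp, the matrix Gla protein that inhibits calcification, rose 4.32-fold, the AMPK-related kinase Nuak2 4.06-fold, macrophage lysozyme Lyz2 3.96-fold and the proliferation marker Mki67 3.90-fold. The nuclear long noncoding RNA Neat1 rose 3.24-fold, collagen Col1a1 3.14-fold, Adgrg3 3.11-fold, the non-gastric proton pump Atp12a 3.10-fold, AY036118 3.0-fold, Lyz1 2.98-fold, Phxr4 2.97-fold, Nfkbiz 2.95-fold, the secreted protease Adamts1 2.79-fold and collagen Col8a1 2.71-fold. Lyz1 and Lyz2 are close paralogs whose probes can share signal. The greatest fall was that of Car3, carbonic anhydrase 3, at 38.6-fold, from 10.64 ± 2.32 to 5.36 ± 0.36 (SD, n = 3 per group; adjusted p = 0.0174). Its saline values were 10.9, 12.8 and 8.17 and its metformin values 5.06, 5.28 and 5.76, and the adipocyte marker scores of the same arrays were 0.72, 1.2 and -0.21 for saline and -0.67, -0.57 and -0.52 for metformin. Sptssb, a subunit of serine palmitoyltransferase, fell 8.80-fold, with saline values of 9.63, 9.50 and 6.36 against 5.69, 5.86 and 4.52 with metformin. The selenophosphate synthetase Sephs2 fell 4.50-fold, the FOXO target Depp1 4.40-fold and C1qtnf3 4.15-fold. Acmsd, which steers tryptophan breakdown away from NAD, fell 4.14-fold, Tldc2 3.99-fold, the glucuronosyltransferase Ugt2b34 3.92-fold, Fabp7 3.82-fold, Lrrc61 3.74-fold, Gpx6 3.59-fold, Igfbp1 3.58-fold, the lipogenic gene Thrsp 3.56-fold, the histamine methyltransferase Hnmt 3.54-fold and the betaine-homocysteine methyltransferase Bhmt 3.49-fold. The limma adjusted p of these 30 genes ran from 0.00667 for Atp12a to 0.0456 for Thrsp. In leave-one-out fits 15 of the 30 calls held each time, among them Nuak2, Neat1, Atp12a, Sephs2, Tldc2, Ugt2b34 and Bhmt. The other 15 ended without saline replicate 1 or without metformin replicate 2, 14 without metformin replicate 1, 7 without saline replicate 3, 6 without metformin replicate 3 and 1 without saline replicate 2, with adjusted p up to 0.151. Without saline replicate 3 the log2 change of Sptssb was -4.21 in place of -3.14 and that of Car3 -6.50 in place of -5.27, and without saline replicate 2 those of Car3, Thrsp and Lyz2 were -4.20, -1.22 and 2.6. With the adipocyte marker score in the fit, an alternative chosen after seeing the data, Sptssb had a change of -0.52 (adjusted p = 0.775) and Car3 of -1.56 (adjusted p = 0.0496). The score correlated with the group at -0.809, so this fit cannot separate fat from metformin. Other changes were larger with the score, such as those of Ccn1 (3.79, adjusted p = 0.0629) and Lyz2 (3.62, adjusted p = 0.0482). Of the 7 calls just named as held, those of Nuak2 (adjusted p = 0.111), Neat1 (0.0571), Sephs2 (0.0708), Tldc2 (0.0597) and Bhmt (0.0776) ended with it. Those of Atp12a and Ugt2b34 stayed. With the replicate number as a block, the adjusted p of Adamts1 was 0.0553.

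**Figure D1:**
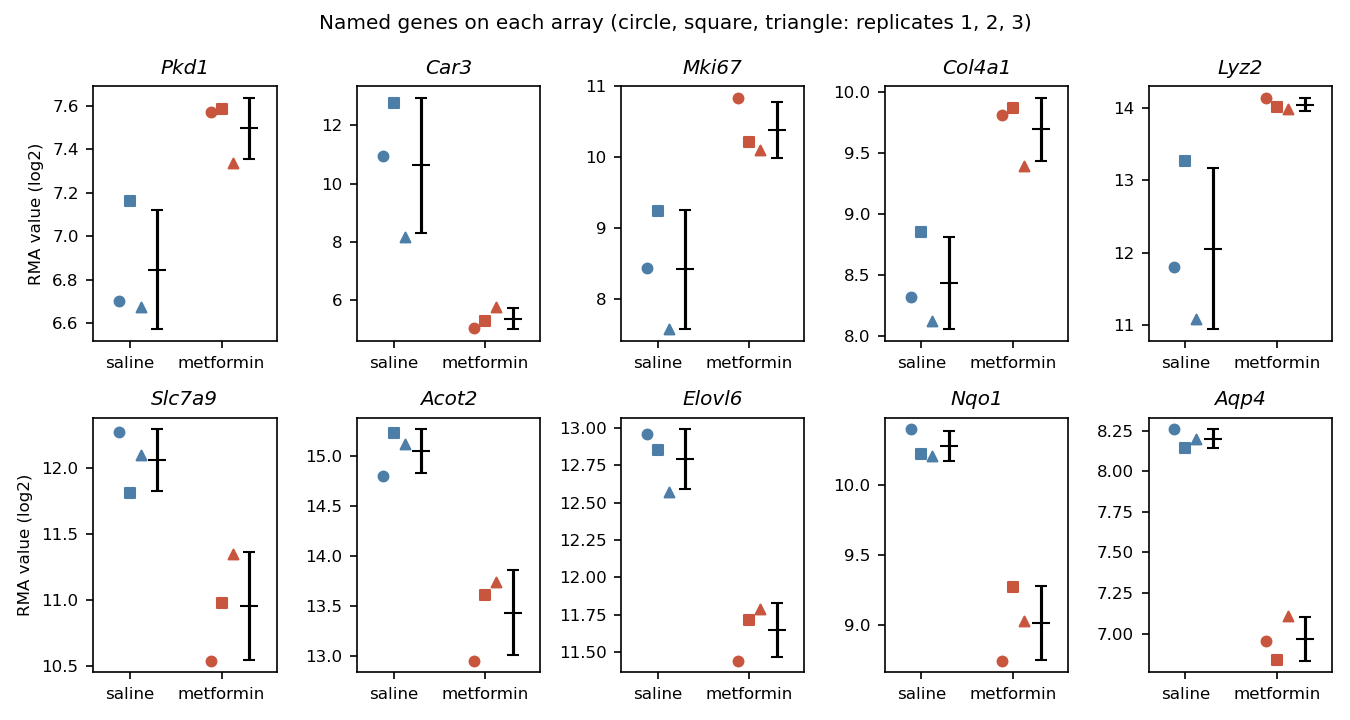
RMA values on the log2 scale of 10 named genes on each array, with replicates 1, 2 and 3 drawn as circle, square and triangle, and the mean ± SD (n = 3) beside each group. The metformin arrays lie above all saline arrays for Pkd1, Mki67, Col4a1 and Lyz2, and below all of them for Car3, Slc7a9, Acot2, Elovl6, Nqo1 and Aqp4.

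Of 30 markers of the proximal tubule, the segment that reabsorbs most filtered solutes, 10 fell and none rose (22 fell and 1 rose when adjusted over the list alone), with a median of -0.76 log2 units. The amino acid transporters Slc7a9 (-1.11 ± 0.21, SE), Slc7a7 (-1.08 ± 0.24) and Slc6a19 (-1.33 ± 0.32) and the lactate transporter Slc5a12 (-0.75 ± 0.16) were among them. In the list of tryptophan, nicotinamide and amino acid metabolism, 17 of 26 fell (19 adjusted over the list alone), no member lay above 0, and the median was -0.78. Those that fell include Bhmt (-1.80), Acmsd (-2.05), aromatic amino acid decarboxylase Ddc (-1.52), kynurenine monooxygenase Kmo (-1.11) and the nicotinamide mononucleotide adenylyltransferase Nmnat1 (-0.60). Of 6 metformin and cation transporters, 5 fell (5 adjusted over the list alone; median -1.0). They include Slc22a4 (-1.31), the thiamine transporter Slc19a3 (-1.19), the basolateral carrier Slc22a2 that takes up metformin (-1.10) and its apical exporter Slc47a1 (-0.84). Of 25 genes of xenobiotic and steroid metabolism, 5 fell (10 adjusted over the list alone; median -0.61), including Fmo2 (-1.11) and the organic anion transporter Slc22a8 (-0.83). The camera test called all 4 lists, with adjusted p of 2.1e-07 for the proximal tubule, 8.12e-10 for amino acid metabolism, 0.00205 for the transporters and 5.85e-05 for xenobiotic genes. With an estimated correlation none was called, each at an adjusted p = 0.578. The proximal tubule score was 0.32, 0.14 and 0.58 on saline arrays 1 to 3 and -0.69, -0.28 and -0.07 on metformin arrays 1 to 3. Of the 15 gene calls named here, 3 held in each leave-one-out fit: 12 ended without saline replicate 1, 10 without metformin replicate 2 and 7 each without metformin replicate 1 and saline replicate 3, with adjusted p up to 0.118.

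Of 30 genes of fatty acid oxidation and PPARA targets 14 fell, none rose and 16 did not pass (22 fell adjusted over the list alone), with a median of -0.52. The camera test called the list (adjusted p = 1.1e-08), with an adjusted p = 0.578 with an estimated correlation. Among the genes that fell were the acyl-CoA thioesterase Acot2 (-1.62), the carnitine-acylcarnitine translocase Slc25a20 (-1.31), the fatty acid transporter Cd36 (-1.29), pantetheinase Vnn1 (-1.2), the trifunctional enzyme subunit Hadhb (-1.11) and the regulator Ppara itself (-1.05). Acot2 has close paralogs whose probes can share signal. Nuclear genes of complex I, the respiratory complex that metformin inhibits, fell in 7 of 32 (11 adjusted over the list alone; median -0.34), with Ndufb9 at -1.07 and Ndufb6 at -0.76. In complexes II to V, 8 of 37 fell (10 adjusted over the list alone; median -0.29), with the succinate dehydrogenase subunit Sdhd at -1.29 and the ATP synthase subunit Atp5d at -0.69. Among 5 genes encoded in the mitochondrial DNA, ND6 rose by 0.83, the only one past the threshold (1 adjusted over the list alone), and the list was not called (median 0.03, adjusted p = 0.477). Of 12 gluconeogenesis genes, 6 fell (6 adjusted over the list alone; median -0.65), among them the glucose-6-phosphate transporter Slc37a4 (-1.63) and the phosphatase G6pc (-1.40). The camera adjusted p was 1.53e-05 for complex I, 4.05e-06 for complexes II to V and 0.00396 for gluconeogenesis. With an estimated correlation these lists had adjusted p = 0.682, 0.609 and 0.609. The 4 list calls of this paragraph held in each leave-one-out fit, and 6 of the 13 gene calls named here did. Without saline replicate 1 the other 7 ended, with 3 ended without metformin replicate 3, 2 each without saline replicate 3 and metformin replicate 1, and 1 each without saline replicate 2 and metformin replicate 2, at adjusted p up to 0.125. With the mean over a gene's clusters, Atp5d had a change of -0.29 (adjusted p = 0.0609), so its value rests on the cluster chosen.

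Of 19 genes of fatty acid and triglyceride synthesis, 9 fell (13 fell and 1 rose adjusted over the list alone; median -0.57), among them Dgat2, the last step of triglyceride synthesis (-1.30), the elongase Elovl6 (-1.14) and malic enzyme Me1 (-0.99). Of 18 genes of cholesterol synthesis and uptake, 5 fell (8 adjusted over the list alone; median -0.40), among them the sterol sensor Insig1 (-1.09), Idi1 (-0.79), Mvd (-0.64) and Mvk (-0.49). Among 13 adipocyte markers 1 fell, adiponectin Adipoq at -1.32 (10 adjusted over the list alone), all 13 lay below 0 and the median was -0.92. Cidec, a lipid droplet protein, had a change of -1.65 (adjusted p = 0.0555, and 0.0488 with the replicate number as a block; -2.25 without saline replicate 3). Brown fat Ucp1, chosen after its values were seen, had a change of -3.61 (adjusted p = 0.0805), with saline values of 7.46, 10.3 and 4.68 against 3.96, 3.74 and 3.91 with metformin, and changes of -5.01 without saline replicate 3 and -2.20 without saline replicate 2. The camera adjusted p was 2.46e-05 for fatty acid synthesis, 6.64e-05 for cholesterol and 0.000262 for adipocyte markers. With an estimated correlation each had an adjusted p = 0.578. Of the 8 gene calls named here, Insig1, Elovl6 and Me1 held in each leave-one-out fit. Without saline replicate 1 the other 5 ended, 4 without metformin replicate 2, 2 without metformin replicate 1 and 1 each without saline replicate 3 and metformin replicate 3, at adjusted p up to 0.145.

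Of 34 cell cycle genes 12 rose and none fell (22 rose adjusted over the list alone), 32 lay above 0 and the median was 0.41. The proliferation antigen Mki67 went from 8.42 ± 0.83 to 10.38 ± 0.40 (SD, n = 3 per group; adjusted p = 0.0211). Topoisomerase Top2a rose by 1.23 ± 0.26 (SE), the kinetochore protein Cenpf by 1.02 ± 0.22, the mitotic kinase Plk1 by 0.92 ± 0.20, cyclin Ccna2 by 0.68 ± 0.15 and survivin Birc5 by 0.58 ± 0.11. The score of the list was -0.23, -0.05 and -0.46 on saline arrays 1 to 3 and 0.37, 0.29 and 0.08 on metformin arrays 1 to 3. The camera test called the list (adjusted p = 1.11e-07), which gave an adjusted p = 0.609 with an estimated correlation. The list call held in each leave-one-out fit, while the 6 genes named each lost theirs without saline replicate 1, metformin replicate 1 or metformin replicate 2, at adjusted p up to 0.0869. With the adipocyte marker score in the fit, an alternative chosen after seeing the data, the list median was 0.62. That score correlated with the group at -0.809, so this fit cannot separate fat from metformin.

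Of 34 genes of extracellular matrix and fibrosis 6 rose (6 adjusted over the list alone; median 0.58), among them the collagens Col1a1 by 1.65 ± 0.42 (SE), the basement membrane chains Col4a1 by 1.27 ± 0.21 and Col4a2 by 1.03 ± 0.21, and Col18a1 by 0.79. Of 25 macrophage markers, all above 0, Lyz2 (1.99 ± 0.48), Lyz1 (1.58 ± 0.33) and the integrin Itgax (0.68 ± 0.17) rose (5 rose adjusted over the list alone; median 0.65). Of 22 tubule injury genes none passed the threshold (0 adjusted over the list alone), with a median of 0.78: the chaperone Clu had a change of 1.0 (adjusted p = 0.0592) and keratin Krt8 of 1.08 (adjusted p = 0.0689). With the replicate number as a block these were called, at adjusted p = 0.0267 and 0.0170. Of 28 genes of NF-kB and inflammatory cytokines none passed (0 adjusted over the list alone; median 0.37), with Nfkb2 at 0.67 (adjusted p = 0.0510, and 0.0354 with the block) and Ccl20 at 0.64 (adjusted p = 0.0530, and 0.0253 with the block). Of 15 genes of MHC and antigen presentation, the peptide transporter Tap1 rose by 0.60 (0 adjusted over the list alone; median 0.17). The camera adjusted p was 7.16e-05 for matrix, 2.64e-05 for macrophages, 0.00243 for injury, 0.000461 for NF-kB and 0.0417 for MHC genes. With an estimated correlation these had adjusted p = 0.743, 0.682, 0.748, 0.735 and 0.791. The macrophage score was -0.49, 0.28 and -0.88 on saline arrays 1 to 3 and 0.57, 0.37 and 0.14 on metformin arrays 1 to 3, so the groups overlapped, as did the scores of the other 4 lists. The MHC call ended without saline replicate 1 (adjusted p = 0.0673), saline replicate 3 (0.408), metformin replicate 2 (0.116) or metformin replicate 3 (0.0817). Of the 8 gene calls named here none held in each leave-one-out fit: 8 ended without saline replicate 1, 7 each without metformin replicates 1 and 2, and 5 each without saline replicate 3 and metformin replicate 3, at adjusted p up to 0.139. With the adipocyte marker score in the fit, an alternative chosen after seeing the data, the medians were 1.42 for matrix, 1.44 for macrophages, 1.76 for injury, 0.76 for NF-kB and 0.58 for MHC genes. The score correlated with the group at -0.809 and varied mostly among the saline arrays (SD 0.736, against 0.078 in metformin). These larger medians therefore do not show a rise apart from fat.

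**Figure D2:**
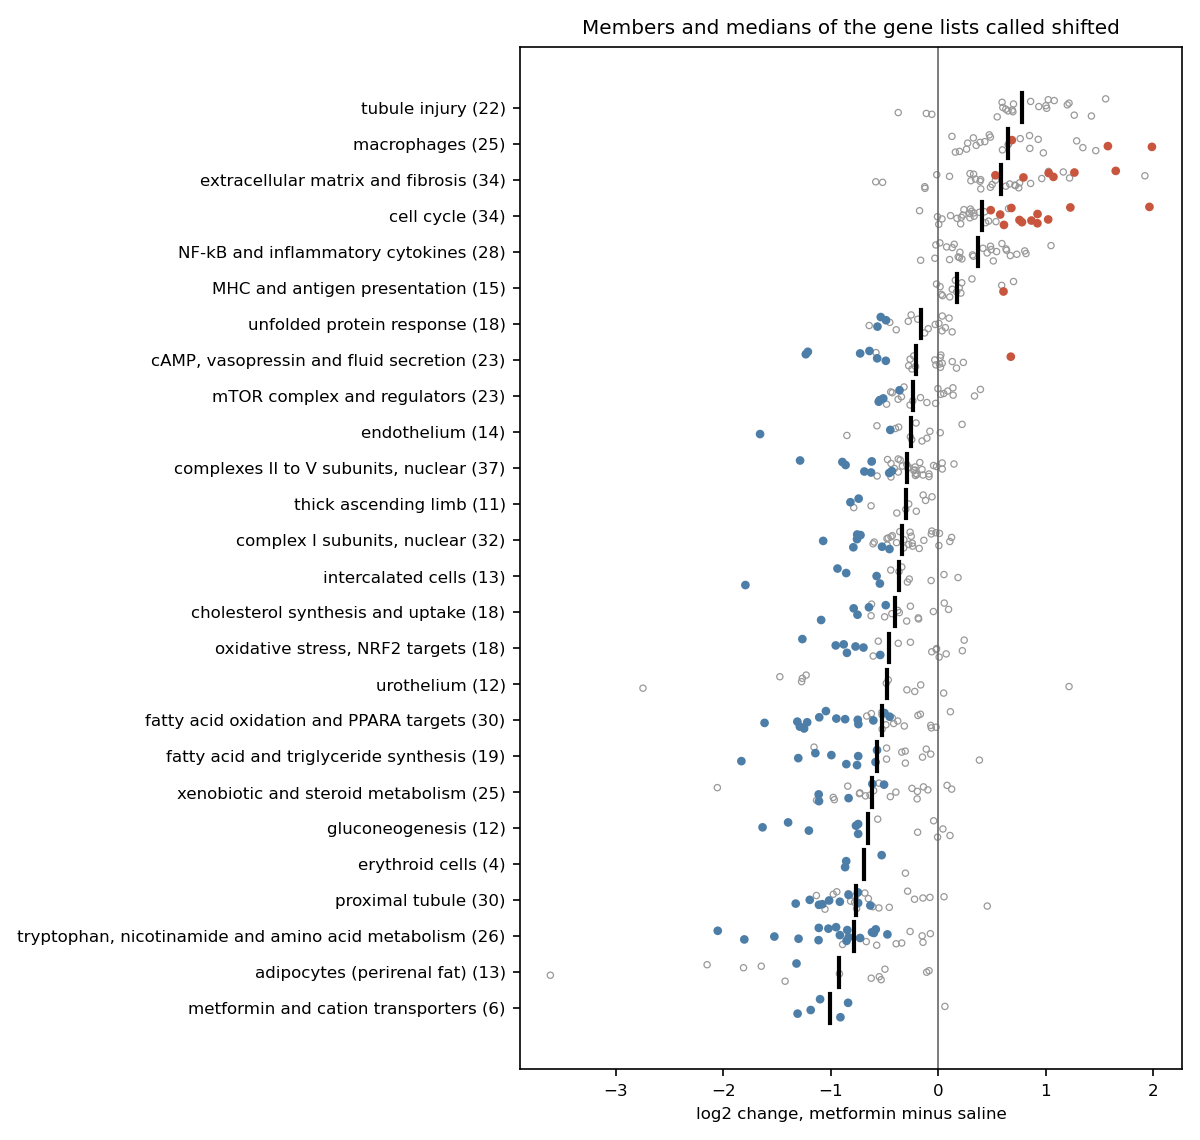
Change of each member (points; filled where the adjusted p is under 0.05) and the median (black bar) of the 26 lists called by camera, in log2 units of metformin minus saline, with the number of measured members in brackets. Medians run from 0.78 for tubule injury to -1.0 for metformin and cation transporters, and 6 lists lie above 0.

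Pkd1, the gene that the transgene targets, was higher with metformin: 6.85 ± 0.27 in saline and 7.50 ± 0.14 in metformin kidneys (SD, n = 3 per group), a change of 0.65 (adjusted p = 0.0317). Of 23 polycystic and ciliary disease genes 5 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.07), and the list was not called (adjusted p = 0.466). Pkhd1, the gene of recessive polycystic kidney disease, rose by 1.20 ± 0.20 (SE) and the RNA-binding protein gene Bicc1 by 0.88 ± 0.20, while the Bardet-Biedl gene Bbs2 fell by 0.48. In the list of cAMP, vasopressin and fluid secretion, 6 of 23 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.21). Those that fell include the water channels Aqp4 (-1.23) and Aqp3 (-0.73), the vasopressin receptors Avpr1a (-1.21) and Avpr2 (-0.64) and the phosphodiesterase Pde1a (-0.49), whereas adenylyl cyclase Adcy6 rose by 0.67. The camera adjusted p was 0.0241, and 0.578 with an estimated correlation. The list call ended without saline replicate 2 (adjusted p = 0.132, median -0.03) and with a stricter filter on dim clusters (0.0648). Among alternatives chosen after seeing the data, it also ended with protein-coding genes only (0.0892) and with the adipocyte marker score in the fit (0.521, median -0.08). Of 24 genes of cyst-associated signalling, Ccn1 and Vegfa rose, by 2.21 and 0.33 (0 adjusted over the list alone; median 0.07), and the list was not called (adjusted p = 0.426). After median-centring the adjusted p of Pkd1 was 0.0592. Of 12 gene calls named here Aqp4 and Avpr1a held in each leave-one-out fit: 9 each ended without saline replicate 1 and metformin replicate 1, 8 without metformin replicate 2, 5 without metformin replicate 3, 4 without saline replicate 3 and 2 without saline replicate 2. The highest adjusted p in those fits was 0.113 for Pkd1 and 0.138 for Ccn1.

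Subunits of AMPK, the energy-sensing kinase that metformin activates, moved in both directions. The regulatory subunits Prkab2 and Prkag2 rose by 0.69 and 0.49, and the catalytic subunit Prkaa2 fell (-0.59). Of the LKB1 complex in the same list, and not AMPK subunits, the scaffold Cab39l (-0.89) and Stradb (-0.54) fell. In the list of 13 AMPK and LKB1 subunits 2 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.05), and it was not called (adjusted p = 0.718). Of 23 genes of the mTOR complex and its regulators 4 fell (7 fell and 1 rose adjusted over the list alone; median -0.24). They include Rragc, a GTPase that brings mTOR to the lysosome (-0.55), and the mTOR inhibitors Castor1 (-0.54) and Sesn2 (-0.51). The camera test called the mTOR list at an adjusted p = 0.0372, and gave an adjusted p = 0.578 with an estimated correlation. Its call ended without saline replicate 2 (adjusted p = 0.135), metformin replicate 1 (0.0603) or metformin replicate 3 (0.0642), and after quantile normalization (0.0717). A stricter filter (0.0905) and array weights (0.0580) ended it as well. So did protein-coding genes only (0.130) and the adipocyte marker score in the fit (0.563), both chosen after seeing the data. Of 8 gene calls named here Cab39l held in each leave-one-out fit: 6 each ended without saline replicate 1, metformin replicate 1 and metformin replicate 2, 4 without saline replicate 3, 3 without metformin replicate 3 and 1 without saline replicate 2, at adjusted p up to 0.118.

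In the thick ascending limb, another kidney segment, 2 of 11 fell (2 adjusted over the list alone; median -0.30), among them the potassium channel Kcnj1 (-0.74). Of 13 markers of acid-base handling intercalated cells 5 fell (6 adjusted over the list alone; median -0.37), including the oxoglutarate receptor Oxgr1 (-1.79), the proton pump subunit Atp6v0d2 (-0.94) and the anion exchanger Slc4a1 (-0.86). Of 14 endothelial markers 2 fell (2 adjusted over the list alone; median -0.25), Ehd3 (-1.66) and the receptor Tek (-0.45). Of 13 erythroid markers 4 were measured, with no globin gene among them. Bpgm (-0.87), Alas2 (-0.53) and Slc4a1, 3 of these 4, fell (3 adjusted over the list alone, median -0.69). Slc4a1 is also in the intercalated cell list, so the erythroid call rests on few genes that do not mark these cells alone. None of 12 urothelial markers passed (0 adjusted over the list alone; median -0.47), with Upk3b at -1.27 (adjusted p = 0.0732) and Psca at -2.75 (adjusted p = 0.130; -4.21 without saline replicate 3, -2.16 without 1 and -1.87 without 2); the urothelial score was 1.05, 0.59 and -0.60 on saline arrays 1 to 3 and -0.20, -0.13 and -0.71 on metformin arrays 1 to 3. The camera adjusted p was 0.00461 for the thick ascending limb, 0.00137 for intercalated cells, 0.00461 for endothelium, 0.00402 for erythroid cells and 0.0315 for urothelium. With an estimated correlation these had adjusted p = 0.578, 0.578, 0.682, 0.578 and 0.748. The endothelial call ended without saline replicate 2 (adjusted p = 0.0693), and the urothelial call without saline replicate 1 (0.132), saline replicate 2 (0.0794) or metformin replicate 3 (0.109). The urothelial call also ended after median-centring (0.102), quantile normalization (0.190) or a stricter filter (0.116). With the adipocyte marker score in the fit, chosen after seeing the data, the endothelial (0.751) and urothelial (0.563) calls both ended. Of 8 gene calls named here 5 held in each leave-one-out fit. The other 3, of Slc4a1, Tek and Alas2, ended without saline replicate 1, metformin replicate 1 or metformin replicate 2, 2 each without saline replicate 3 and metformin replicate 3, and 1 without saline replicate 2, at adjusted p up to 0.121.

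**Figure D3:**
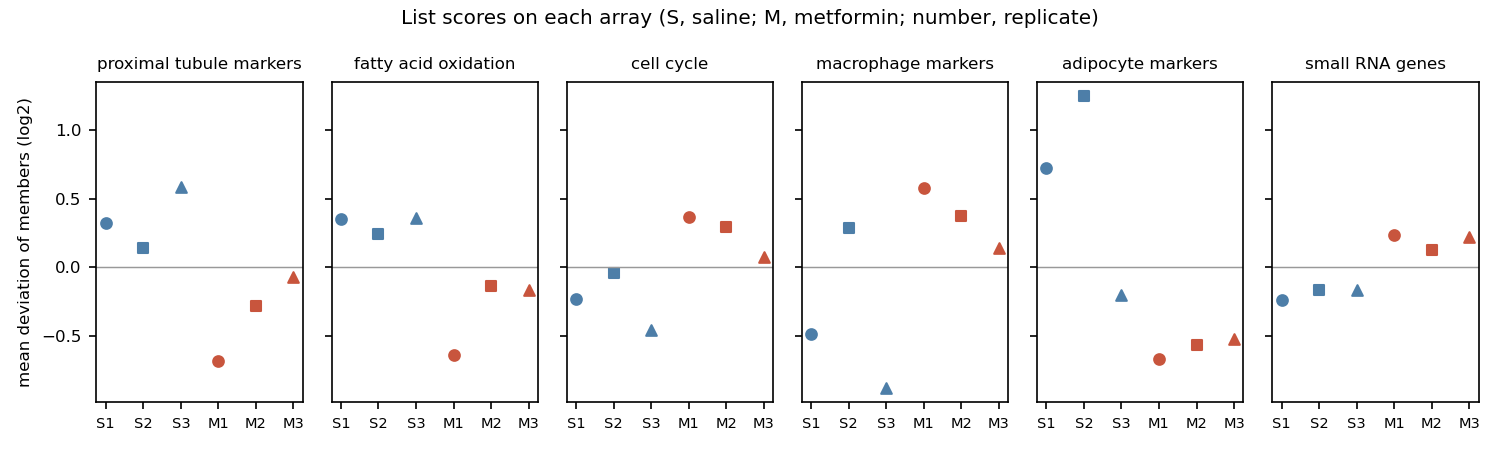
Mean deviation of the members of 6 gene sets from each gene's mean over the 6 arrays, in log2 units, for saline (S) and metformin (M) replicates 1 to 3. Proximal tubule, fatty acid oxidation, cell cycle, adipocyte and small RNA scores do not overlap between the groups, while the macrophage scores do, with saline replicate 2 at 0.28 and metformin replicate 3 at 0.14.

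Of 18 NRF2 targets 7 fell (9 adjusted over the list alone; median -0.46), among them the quinone reductase Nqo1, from 10.27 ± 0.11 to 9.01 ± 0.26 (SD, n = 3 per group), and the glutathione transferases Gsta3 (-0.95) and Gstm1 (-0.77). The transferases have close paralogs whose probes can share signal. Of 18 genes of the unfolded protein response 3 fell (3 adjusted over the list alone; median -0.16), among them Edem1 (-0.57) and the transcription factor Xbp1 (-0.54). The camera adjusted p was 0.00146 for NRF2 targets and 0.0288 for the unfolded protein response, and 0.578 and 0.609 as adjusted p with an estimated correlation. Without saline replicate 2 or metformin replicate 3 the unfolded protein response was no longer called (adjusted p = 0.0619 and 0.109). A stricter filter (0.0708) and, chosen after seeing the data, protein-coding genes only (0.0892) ended its call as well. With the adipocyte marker score in the fit, also chosen then, neither NRF2 targets (0.0600) nor the unfolded protein response (0.115) were called. Among 22 genes of the integrated stress response 6 fell (6 fell and 1 rose adjusted over the list alone; median -0.05), with Psat1 of serine synthesis at -0.94 and Slc3a2 at -0.79, and the list was not called (adjusted p = 0.0680). It was called without saline replicate 3 (adjusted p = 0.0174) or metformin replicate 2 (0.0296). Heat shock genes had 1 of 10 fallen, Hsph1 at -0.81 (1 adjusted over the list alone; median -0.21, adjusted p = 0.0833, and 0.0288 without saline replicate 3). Autophagy and lysosome genes had 6 of 23 fallen (7 fell and 1 rose adjusted over the list alone; median -0.05, adjusted p = 0.113), among them Atg12 (-0.64) and cathepsin Ctsb (-0.69). Glycolysis genes had 5 of 19 fallen and 1 risen (6 and 1 adjusted over the list alone; median -0.12, adjusted p = 0.113, and 0.0248 without metformin replicate 2), with the aldolase Aldoc at -1.23 and the lactate dehydrogenase Ldha at -0.57. Of 18 hypoxia genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; median -0.04, adjusted p = 0.477), with Ero1a at -0.63. Of 16 p53 targets and cell death genes 2 fell (2 adjusted over the list alone), with cyclin Ccng1 at -1.06. The p53 list was not called (adjusted p = 0.589), and its median, 0.01, and its mean, -0.05, differ in sign. Of 14 gene calls named here 8 held in each leave-one-out fit: the other 6 ended without saline replicate 1, 2 each without metformin replicates 1 and 2, and 1 each without saline replicate 2 and metformin replicate 3, at adjusted p up to 0.103.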

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

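Outside the gene comparison, 4377 transcript clusters with no or several gene symbols changed in a limma test of all 43971 clusters past the filter, at an adjusted p under 0.05. They are listed here because the report uses only their counts and names none of them, and their signal differs from that of the saline controls. Of the 21547 such clusters tested 4073 were higher and 304 lower with metformin. No explanation was tested for the unnamed clusters.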

How the results depend on the processing

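The fit on protein-coding genes, the count of identical values once (3300 genes, 1329 higher and 1971 lower) and the fat score in the fit were chosen after seeing the data. Leaving out 1 replicate gave 842 to 3961 changed genes, 2159 to 3364 past the unadjusted threshold and 23 to 28 lists. Of the 3488 changed genes 832 were also called without saline replicate 1. None changed sign in any leave-one-out fit, but none could, since the groups did not overlap in any of the 3488. Fewer arrays lower the power of such a fit. The plain equal-variance test per gene, which does not share the spread between genes, called 44 genes. All clusters, named or not, gave 7774 changed clusters (5553 higher, 2221 lower) and 7169 past the unadjusted threshold with 1.5-fold; 4377 of the 7774 have no or several symbols, 4073 of them higher. At 2-fold in place of 1.5-fold 564 genes passed. Among protein-coding genes 1696 passed the unadjusted threshold with 1.5-fold (440 higher, 1256 lower), from fewer genes. With the estimated correlation 0 lists were called, and with fry 5, which asks another question. The fat score correlated with the group at -0.809, so its fit cannot separate fat from metformin. With the fat score 212 genes were called (141 higher, 71 lower). Of the 40 genes named as largest changes or for lipids, 29 had a wider error with it and 11 a narrower. Over the whole text 107 of the 126 calls of named genes ended with this score. Those of Thrsp and Adipoq ended as their changes went to -0.11 and -0.01. Others ended on larger changes, such as Neat1 at 1.85 against 1.70 (limma adjusted p = 0.0571) and Idi1 at -1.07 against -0.79 (0.0795). The fat score ended the list calls of NRF2 (adjusted p = 0.0600, median -0.40 against -0.46 without it), cAMP (0.521, -0.08 against -0.21), mTOR (0.563, -0.06 against -0.24), unfolded protein response (0.115, -0.11 against -0.16), endothelial (0.751), adipocyte (0.537) and urothelial (0.563) genes. It added those of cyst signalling, interferon, complement, immediate early, ribosomal protein, fibroblast, smooth muscle and T cell genes, all upwards. Of lists called in both fits, medians moved over 1.5 times for macrophage (1.44 against 0.65), matrix (1.42 against 0.58), injury (1.76 against 0.78), NF-kB (0.76 against 0.37), MHC (0.58 against 0.17), cell cycle (0.62 against 0.41), thick ascending limb (-0.61 against -0.30), fatty acid synthesis (-0.34 against -0.57) and xenobiotic genes (-0.40 against -0.61). The replicate block gave 4370 genes and 26 lists, and changed no other call of a gene named in the text, or of a list, than those given there. Apart from this block, the leave-one-out fits and the fat score, other alternatives ended further calls of named genes. With median-centring these were Ccn1, Col1a1, Nfkbiz, Col8a1, Itgax, Tap1, Pkd1, Vegfa, Prkag2 and Blnk. With quantile normalization they were Col8a1, Itgax, Tap1, Vegfa and Blnk. Without the filter they were Ccn1, Nfkbiz, Adamts1, Col8a1, Sptssb, Thrsp, Adipoq, Myh11 and Blnk. Calls of Vegfa, Prkaa2 and Blnk ended with trend and robust options, and that of Atp5d with the mean over clusters. A list is said to reverse by the direction of its camera test, and the values in brackets are medians, which need not change sign. This direction reversed for interferon genes with median-centring (-0.0909), a stricter filter (-0.000578), array weights (0.0287) and protein-coding genes (-0.0288). It also reversed for AMPK with quantile normalization (-0.165) and protein-coding genes (-0.0486), and for the distal tubule with protein-coding genes (0.0549). None of these was called in either setting. With the fat score, the changes of Ucp1 (0.759), Cidec (0.0854), Upk3b (0.130) and Psca (1.12) reversed. So did the test directions of the lists of AMPK (0.0520), mitochondrially encoded (-0.106), p53 (0.104), interferon (0.498), hypoxia (0.0708), principal cell (0.173), podocyte (0.0416), endothelial (0.108), adipocyte (0.0854), adrenal (0.0129) and urothelial (-0.0533) genes. Of uncalled lists, leave-one-out medians ran from -0.0594 to 0.0837 for p53, -0.187 to 0.195 for interferon, -0.142 to 0.513 for complement, 0.0626 to 0.281 for glucocorticoid, -0.0848 to 0.102 for distal tubule, -0.0206 to 0.222 for fibroblast and -0.190 to 0.0988 for smooth muscle genes, each with a reversed test direction in at least 1 fit. The list calls of cAMP, unfolded protein response and urothelial genes ended with the stricter filter and with protein-coding genes, the mTOR call with these and with array weights, the urothelial call also with either scaling, and the MHC call with quantile normalization (adjusted p = 0.114). Without the filter the autophagy (adjusted p = 0.0418), glycolysis (0.0425), heat shock (0.0324) and integrated stress response (0.0215) lists were called, with quantile normalization autophagy (0.0371) and the integrated stress response (0.0455), and with protein-coding genes the ribosomal proteins (0.0428). The cause of these changes was not tested.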

Other observations

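Of 1853 small nuclear, ribosomal, nucleolar, guide and micro RNA genes tested 549 rose and 3 fell, with a median change of 0.32 (bootstrap over genes 0.30 to 0.34). Some have values identical to another gene's. Counted once, a choice made after seeing the data, they form 1705 profiles, of which 427 rose and 3 fell, with a median of 0.299 (0.279 to 0.316). That median was 0.479 for 23 ribosomal RNA profiles (0.760 over all 62 genes), 0.456 for 654 small nuclear, 0.248 for 30 guide RNA, 0.238 for 619 small nucleolar and 0.229 for 379 micro RNA profiles. As 1 set, also chosen then and not adjusted over the lists, these profiles had a camera p of 9.25e-24, and p = 0.00795 with an estimated correlation. Snora62 rose by 4.13 and Snora75 by 4.38, both chosen after their values were seen, from 9.85 ± 0.16 to 13.98 ± 0.21 and from 8.64 ± 0.54 to 13.02 ± 0.23 (SD, n = 3 per group). Of RNAs retained in the nucleus, also chosen then apart from Neat1, Neat1 rose by 1.70 and Xist by 1.0, while Malat1 had a change of 0.30 (adjusted p = 0.0538). These 4 calls held in each leave-one-out fit.

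Among lists not described above, none was called. The glucocorticoid target Klf9 fell by 1.22, 1 of 14 in its list (1 adjusted over the list alone; median 0.16, adjusted p = 0.528), and the clock gene Nr1d1 fell by 1.08, 1 of 2 fallen in 16 clock genes (2 adjusted over the list alone; median -0.15, adjusted p = 0.477). The antiviral gene Rsad2 fell by 1.04 among 26 interferon genes (1 adjusted over the list alone; median -0.0006, adjusted p = 0.890). Rps4x rose by 0.85 among 25 ribosomal protein genes (1 adjusted over the list alone; median 0.11, adjusted p = 0.138, and 0.0441 without saline replicate 2). Complement factor Cfb fell by 0.52 among 13 complement genes (0 adjusted over the list alone; median 0.19, adjusted p = 0.604, and 0.0265 without saline replicate 2). Of 19 immediate early genes none passed (0 adjusted over the list alone; median 0.23, adjusted p = 0.210, and 0.0257 without saline replicate 2 or 0.0429 without metformin replicate 3). Col1a1 rose among 12 fibroblast and pericyte markers (0 adjusted over the list alone; median 0.16, adjusted p = 0.477, and 0.039 without saline replicate 2). Aqp4, Aqp3 and Avpr2 fell among 15 principal cell markers (3 adjusted over the list alone; median -0.36, adjusted p = 0.238, and 0.0254 without saline replicate 3). In smooth muscle, Smtn rose by 0.59 and Myh11 fell by 0.87 of 10 (2 and 1 adjusted over the list alone; median -0.06, mean 0.02, adjusted p = 0.813). Blnk rose by 0.64 of 11 B cell markers (0 adjusted over the list alone; median -0.01, mean 0.07, adjusted p = 0.604). None passed among 13 distal tubule markers (median 0.05, mean -0.03, adjusted p = 0.780), 12 podocyte markers (median -0.10, adjusted p = 0.477), 5 neutrophil markers (median 0.27, adjusted p = 0.528), 19 T and NK cell markers (median 0.09, adjusted p = 0.236) or 8 adrenal markers (median 0.08, adjusted p = 0.700), and each of these gave 0 adjusted over the list alone. Of the 16 gene calls in these lists and among the RNAs above, 10 ended without saline replicate 1, 8 each without metformin replicates 1 and 2, 6 without metformin replicate 3, 4 without saline replicate 2 and 3 without saline replicate 3, at adjusted p up to 0.139.

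The tests of small RNA classes as a set, of small RNA recovery, of the proximal tubule share, of fat and of the splits for both gene counts were chosen only after the result was seen. The rise of small RNAs is not accounted for by a shift between arrays as a whole, since the median stayed at 0.197 (0.182 to 0.220) under quantile normalization, from 0.32. Carry-over of genomic DNA cannot be told apart here: olfactory receptor genes, mostly silent in kidney, had a median change of 0.0487 (0.0370 to 0.0580), but their median level of 3.65 lies under the filter limit of 4.03, so the bound set in advance was wrong in taking genes near the floor as a measure. Different recovery or quality of small RNA in the preparations of the groups cannot be told apart from a change of these RNAs with metformin: all 5 classes had medians above 0, which either would give, so this lends neither any support.

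Lower proximal tubule and metabolic genes beside higher macrophage and matrix genes may have more than 1 source. A trend with intensity is argued against for the proximal tubule, whose median of -0.76 lay at percentile 0 of 10000 random lists matched on intensity (95% of them between -0.31 and 0.11), but 7 of the 26 called lists lay inside the central 95% of theirs and are left open: unfolded protein response (percentile 33.5), thick ascending limb (9.66), endothelium (7.23), mTOR (4.96), intercalated cell (3.95), cAMP (2.79) and MHC genes (95.1). A lower share of proximal tubule cells alone would raise other cell types alike. Macrophage markers lay 0.925 (0.654 to 1.22) above those of endothelium and thick ascending limb. That interval is over genes, not animals, and the macrophage scores overlapped between the groups, so the test does not decide this. Differences in severity between single animals remain open. Once the main axis of variation within groups, 49.6% of that variance, was removed, the median of macrophage, matrix and injury genes went from 0.67 to 0.232 (0.171 to 0.337). Proximal tubule and amino acid genes kept -0.547 (-0.616 to -0.422) of -0.76. The rest of the variance within groups was not removed and the intervals are over genes, so severity stays open for these genes too. A metformin effect on tubule genes stays a hypothesis, since RNA quality and dissection were not tested for these genes.

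Lower lipid synthesis genes came with lower adipocyte markers, and fat attached to the saline kidneys could contribute. With the adipocyte marker score in the fit, the median of fatty acid synthesis genes without adipocyte markers was -0.337 (-0.858 to -0.0789) against -0.57, and that of cholesterol genes -0.553 (-0.859 to -0.409) against -0.40. The score correlated with the group at -0.809 and the intervals are over genes, so this fit cannot separate fat from metformin. The share of fat stays open. With the score Thrsp had a change of -0.11 (SE 0.33) against -1.83 (0.49), while the calls of Elovl6 at -0.86 (0.22) against -1.14 (0.14), Insig1 at -0.78 (0.17) against -1.09 (0.12), Dgat2 at -1.17 (0.46) against -1.30 (0.26) and Me1 at -1.29 (0.23) against -0.99 (0.15) ended with wider errors, for all but Me1 on smaller changes. With the score 14 lists were called up and 13 down, against 6 and 20, both synthesis lists among them, though without it these had an adjusted p = 0.578 with an estimated correlation.

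The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3488 changed genes and the highest of the others 0, so 1 of 10 splits gave as many. For the unadjusted count these were 2629 and 686, again 1 of 10, with 686 from saline replicates 1 and 3 with metformin replicate 3. For lists the real split gave 26 and the highest other 32, and 2 of 10 splits gave as many. The other splits ranged from 9 to 32 lists, so the number of lists called by camera does not set the real split apart. Saline replicates 1 and 2 with metformin replicate 2 made the split of 32 lists. The 3 other splits that part the saline and metformin arrays of every replicate number gave 0 genes, 13 to 92 genes past the unadjusted threshold and 9 to 25 lists.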
